A study of Homo sapiens with 8 samples.

How the data were processed

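Total RNA of 786-O cells transfected with Bcl-xAS or with empty vector was labelled from 200 ng per sample and hybridised to Agilent two-colour expression arrays, per the labels' protocols. All 8 arrays lay on 1 slide. Image analysis used Feature Extraction 10.7.1.1 with an array grid on genome build hg19, per the file headers. The deposited scanner files give the intensity of each spot as the median pixel brightness in the red and the green channel, without background correction, with the median local background beside it. They also give a log10 ratio of red over green, which the authors' scanner software background-subtracted and dye-normalized, per the file headers. The deposited series value table holds log2 ratios per spot. Set against the scanner log ratios of the same array (in log2, turned to Bcl-xAS over empty vector), its columns correlated with r between 0.959 and 0.999 and lay within 0.01 for 91.0% to 94.3% of the non-control spots. That settles its scale and direction. Its column medians were -0.00 and 0.02 for replicate 1 in the Cy5 and the Cy3 orientation, -0.01 and 0.01 for replicate 2, -0.06 and -0.01 for replicate 3, and -0.06 and 0.02 for replicate 4, and any further centring by the authors is not given in the sources used here.

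From the intensity columns, each channel was background-corrected with normexp (offset 50) in limma 3.58.1 under R 4.3.3, and files were read with the R package data.table, version 1.17.8. Mean signals had been planned, but the files hold median signals, which were used instead. Each array was normalized by loess (span 0.3) with control spots and outlier spots at weight 0. Outlier spots, 759 to 1645 per array, were then left out, spots of a probe were averaged, and arrays with Bcl-xAS in Cy3 were turned. A probe was tested if it was well above background on at least 4 of 8 arrays in the channel of at least 1 RNA and had values in at least 3 replicates, which left 33558 of 42405 probes. The ratio averaged over both arrays of a replicate number was tested against 0 with lmFit and eBayes, and p-values were adjusted by the Benjamini-Hochberg method over all tested probes (threshold 0.05). The offset of normexp shrinks the ratios of dim probes. A bound for a probe that was not well above background in 1 RNA on any array compares the mean of the brighter RNA with the mean of the higher of the dim signal and the lowest signal well above background, after loess and Aquantile.

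Probes carry RefSeq accessions, of which 24826 of 27448 (90.4%) matched a symbol in a table of assembly GRCh38.p14, used only for names. Probes without a match were tested but not named. Of several probes of a gene the brightest stood for the gene, giving 16193 genes. Among 3812 genes with several tested probes the median range between probes was 0.20 on the log2 scale and the 95th percentile 0.96, and 17 genes had probes at least 1.5-fold changed in opposite directions. A planned search for probes positioned within the BCL2L1 locus was not made, because no hg19 annotation was used here. No level was taken for Bcl-xAS, since no probe was matched to it.

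Gene lists, the naming rule and the tests were fixed before the data were examined. Named genes are, per direction, the 12 of largest log2 ratio among those past the threshold with the same sign in all 4 replicates, the 3 lincRNA probes of smallest p per direction, BCL2L1, and the 4 members of smallest p in each of 24 lists, of which a few are left out of the text. Lists were tested with camera (preset correlation 0.01, two-sided, Benjamini-Hochberg over the 24 lists), with an estimated correlation and with fry as alternatives. The lists were those named in the results, and 717 of their 723 entries matched a symbol. An estimated correlation rests on 3 residual degrees of freedom here.

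Both RNAs of a replicate number shared an array, so the ratios are paired by hybridisation. As a check, deviations of the Bcl-xAS and empty vector channel levels from their group means correlated with r between 0.826 and 0.901 in the 4 replicate numbers, which includes what the spots of an array share. Without the replicate block, with the RNAs unpaired, 8144 genes passed. Differences between replicates were compared across the 2 dye orientations: for replicates 2 and 4 they correlated with r = 0.03, and for replicates 1 and 3 with r = -0.01 over all tested probes and 0.28 over probes brighter than 11 on the log2 scale, against 0.02 for replicates 2 and 4. Replicates of different slide columns gave r between -0.31 and -0.12 over all tested probes and between -0.68 and -0.05 over the brighter ones; the cause was not tested. Residuals of the 2 orientations of one replicate number correlated with r between -0.21 and -0.07. These values do not show 4 separate RNAs per condition, so n = 4 rests on the labels, and the fit with replicates 2 and 4 counted as 1 was added after seeing the data.

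The steps were tested on simulated data. Arrays drawn with 200 of the probes changed (33558 tested) gave 50 of 50 probes recovered at each of 1.25-fold, 1.5-fold, 2-fold and 4-fold in the comparison of Bcl-xAS with empty vector, and 3 of 33358 other tested probes were called. A simulated 2-fold change came out at 1.73-fold on average, and at 1.93-fold among the brighter probes. In simulated ratios of 16193 genes, 1 list raised among 24 was called, with 1 list that shares genes with it and 0 others. The noise drawn was independent between spots and between genes, and far fewer probes were changed than the 23317 called in the real data. These counts therefore do not measure false calls in the real data, or the camera test where genes are correlated. Alternatives tried were the background correction and its offset, the within-array and between-array normalization, the filter on dim probes, the scanner log ratios, the series value table, each dye orientation alone, each replicate left out, the variance model, the slide column, the probe rule and the threshold. Scaling to the spike-in RNAs, each slide column alone and an adjustment over genes alone were added after seeing the data.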

Results

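The study measured what changes in the RNA of 786-O cells, a line from a clear cell renal carcinoma that lacks a working VHL protein, when they carry extra Bcl-xAS, a long non-coding RNA transcribed antisense to the Bcl-x gene (BCL2L1). Cells received 6 μg of a Bcl-xAS expression plasmid or of the empty vector with the transfection reagent FuGENE HD, and total RNA was taken 24 h later. RNA from 4 plates per condition, grown in parallel, was compared on 8 two-colour microarrays: each replicate number was hybridised once with Bcl-xAS in the red dye (Cy5) and once in the green dye (Cy3). Both arrays of a replicate number were averaged into 1 log2 ratio of Bcl-xAS over empty vector, so n = 4. The exceptions are 194 tested probes with values in 3 replicates. Between 70.6% and 82.9% of the non-control spots were well above background in a channel, and no spot was saturated. The plates came from 1 cell line handled together, so p-values measure no more than the spread between these parallel plates and their arrays. Residuals of the 2 orientations of one replicate number correlated with r between -0.21 and -0.07. A spread between plates was therefore not seen apart from that between arrays. The number of arrays limits the precision.

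Most of the genes with the largest rise in Bcl-xAS belong to the interferon-stimulated list. RSAD2, which encodes the antiviral protein viperin, stood at a log2 ratio of 5.56 ± 0.09 (SD, n = 4), a 47.2-fold rise. The antiviral GTPase genes MX2 and MX1 rose by 37.6-fold and 19.5-fold, with log2 ratios of 5.23 ± 0.08 and 4.28 ± 0.06. CMPK2, a nucleotide kinase gene, rose by 28.2-fold and the chemokine gene CCL5 by 26.6-fold. IFI6, the oligoadenylate synthetase family genes OASL and OAS1, the exonuclease gene ISG20 and IFI44L rose by 25.4-fold, 24.9-fold, 16.0-fold, 20.3-fold and 16.7-fold. C1S, a serine protease of the complement cascade, had a log2 ratio of 4.77 ± 0.11 on its brighter probe and 0.67 on its other tested probe. ANGPTL4, a secreted inhibitor of lipoprotein lipase, rose by 15.9-fold. Each of these 12 genes was higher in 4 of 4 replicates, with limma adjusted p between 3.38e-15 and 4.83e-14.

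The genes of largest fall moved less. RFLNB, which encodes an actin-bundling partner of filamin, had a log2 ratio of -2.21 ± 0.06 (SD, n = 4), so that it was 4.64-fold lower. ACO1, the cytosolic aconitase that also acts as an iron sensor, was 4.59-fold lower, at a log2 ratio of -2.20 ± 0.04. ACTR3C, the long non-coding RNA DANCR and the Rab escort protein gene CHML had log2 ratios of -2.07 ± 0.04, -1.95 ± 0.07 and -1.87 ± 0.04. ARL3, a small GTPase gene of cilia, stood at -1.86 ± 0.32, the widest spread of the 12. ASAP1-IT1, VAV3, the histone gene H4C11 and NT5DC2 had log2 ratios of -1.78 ± 0.06, -1.75 ± 0.08, -1.72 ± 0.23 and -1.71 ± 0.08. AGPS, an enzyme gene of ether lipid synthesis, and PMEPA1 had log2 ratios of -1.73 ± 0.07 and -1.66 ± 0.05 on their brightest probes, while other tested probes of AGPS lay between -0.43 and -0.25 and that of PMEPA1 at -0.15. All 12 fell in 4 of 4 replicates, with adjusted p between 1.85e-13 and 4.58e-09.

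**Figure D1:**
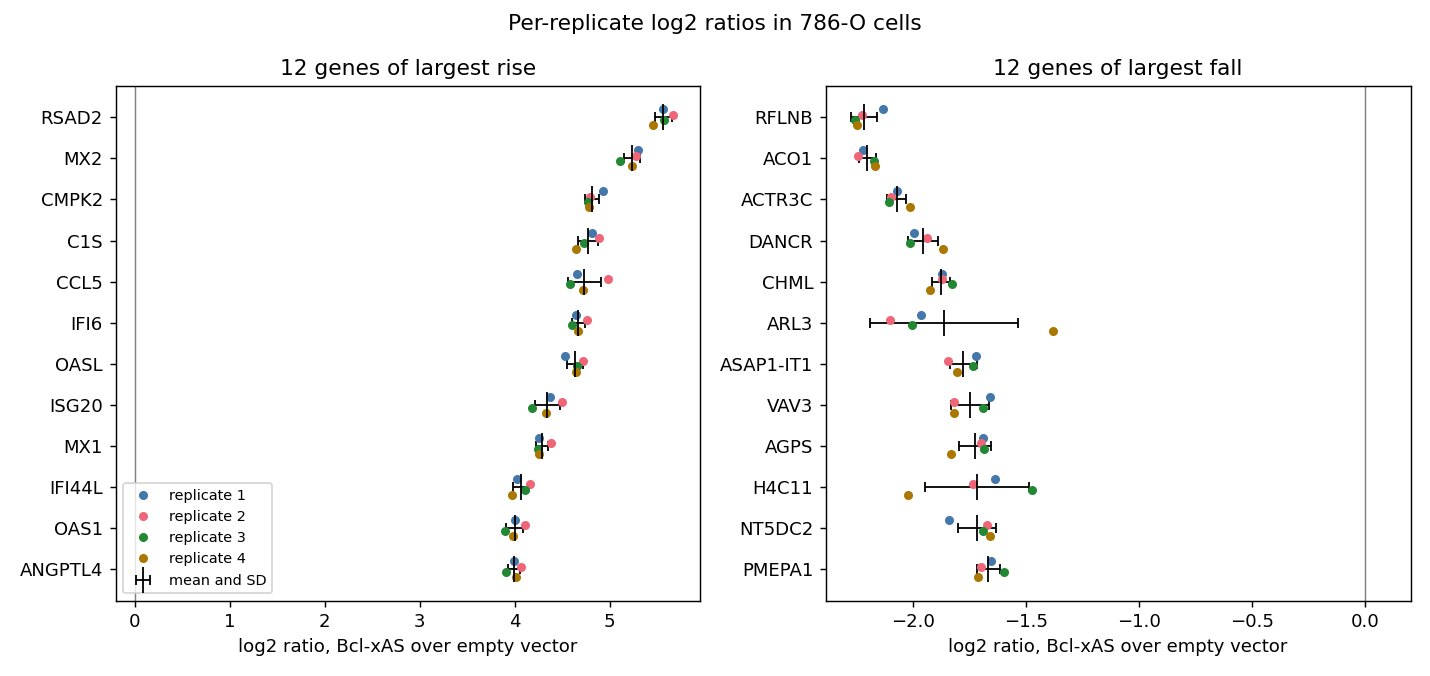
Log2 ratio of Bcl-xAS over empty vector (x axis) for the 12 genes of largest rise (left) and of largest fall (right), 1 row per gene; points are the 4 replicates, each averaged over both dye orientations, and bars are the mean and SD. The rises reach a log2 ratio of 5.56 for RSAD2, while the falls reach -2.21 for RFLNB.

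Across the array, 12020 of 16193 tested genes passed adjusted p 0.05, 6570 higher and 5450 lower in Bcl-xAS. Most of these differences were below 1.5-fold, and the median SD between replicates was 0.06 on the log2 scale. At least 1.5-fold changes were seen for 1609 genes that rose and 936 that fell, and 642 rose and 175 fell by at least 2-fold. The excess of rises at 1.5-fold turned round with median centring, to 1204 higher and 1627 lower, and with spike-in scaling, to 728 higher and 3253 lower. Of the 2545 genes changed by at least 1.5-fold, 2522 had the same sign in all 4 replicates. The balance of directions depended on the scaling: 54.7% of the calls were higher here, 43.8% when each array was centred on its median, and 13.7% when ratios were scaled to the spike-in RNAs, a setting chosen after seeing the data that moved the median of all genes by -0.35. Directions below are therefore relative to the bulk of the genes on the array. Over all tested probes no difference between 2 replicate numbers recurred across the dye orientations (r between -0.31 and 0.03 for the 6 pairs), so n = 4 rests on the labels. Counting replicates 2 and 4 as 1 sample, a setting chosen after seeing the data, left 1600 genes at least 1.5-fold higher and 928 lower. These counts do not test whether the replicate numbers are separate RNAs, since no other pair recurred either.

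Every tested member of the interferon-stimulated list rose: 42 of 42 genes, with 40 at least 1.5-fold higher, over all probes and adjusted over the list alone. The list median was 3.15 ± 0.07 (SD, n = 4), an 8.85-fold rise, and the limma camera test gave adjusted p = 4.59e-21 with its preset correlation. With the correlation estimated from the 4 replicates the adjusted p = 0.123 for this list. The median was 3.07 on the arrays with Bcl-xAS in Cy5 and 3.14 on those with Bcl-xAS in Cy3, and 3.10 and 3.18 in the 2 slide columns. With spike-in scaling 40 of the 42 rose and 0 fell past the threshold, at a median of 2.79.

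Inflammatory, stress and immediate early genes rose as groups. Some lists share genes, such as ATF3 in the immediate early and the stress response lists. No list was tested without its shared genes, so the calls of different lists are not independent. Of 27 tested NF-kB inflammatory genes, 24 rose and 2 fell (24 and 2 adjusted over the list alone), with a median log2 ratio of 1.04 ± 0.02 (SD, n = 4) and camera adjusted p = 2.63e-07 (adjusted p = 0.123 with an estimated correlation). With spike-in scaling 17 rose and 4 fell, and the median moved to 0.69. Its members included CCL5, the mitochondrial superoxide dismutase gene SOD2 at 2.14 ± 0.03, and the cytokine genes CXCL2 and IL6 at 1.91 ± 0.08 and 1.63 ± 0.02. In the immediate early list 22 of 28 rose and 3 fell (22 and 3 adjusted over the list alone; camera adjusted p = 1.16e-05, and adjusted p = 0.123 with an estimated correlation), led by the transcription factor genes ATF3 and KLF4 at 3.60 ± 0.03 and 2.90 ± 0.08. With spike-in scaling 16 of these rose and 6 fell, and the list median moved from 0.57 to 0.22. The phosphatase genes DUSP5 and DUSP6, which act on MAP kinases, stood at 2.43 ± 0.04 and 1.44 ± 0.08. Of 27 genes of the unfolded protein and integrated stress response, 23 rose and 1 fell (23 and 2 adjusted over the list alone; camera adjusted p = 5.73e-06, and adjusted p = 0.184 with an estimated correlation). With spike-in scaling 11 rose and 6 fell in this list, and its median moved from 0.50 to 0.15. DDIT3, PPP1R15A and CEBPB had log2 ratios of 2.18 ± 0.08, 1.82 ± 0.04 and 1.57 ± 0.04. Other tested probes of ATF3 ranged from 0.15 to 2.66.

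Metabolic and degradative groups also moved upwards. HIF target genes rose in 25 of 32 cases and fell in 4 (25 and 4 adjusted over the list alone), with a median of 0.73 ± 0.04 (SD, n = 4) and camera adjusted p = 1.16e-05 (adjusted p = 0.123 with an estimated correlation). With spike-in scaling 18 rose and 9 fell, and the median moved to 0.37. NDRG1 and the hexokinase gene HK2 stood at 1.59 ± 0.06 and 1.29 ± 0.02. In the autophagy and lysosome list 22 of 26 rose and 2 fell (22 and 2 adjusted over the list alone; camera adjusted p = 3.51e-05, and adjusted p = 0.123 with an estimated correlation). Its members included the cathepsin gene CTSL, the lysosomal sialidase gene NEU1 and the autophagy receptor gene SQSTM1, at 1.39 ± 0.04, 1.18 ± 0.04 and 1.08 ± 0.08. With spike-in scaling 11 rose and 8 fell in this list, and its median moved from 0.36 to 0.0078. Spike-in scaling takes the same value from every gene of a replicate, so differences between genes within a replicate stay as they were. Camera compares a list with other genes, so its call upwards there (adjusted p = 0.00014) does not test the scaling. A camera p can change there only because each ratio is set against its spread between replicates. In the metallothionein and oxidative stress list 15 of 19 rose and 2 fell (15 and 2 adjusted over the list alone; camera adjusted p = 0.00853, and adjusted p = 0.137 with an estimated correlation). HMOX1, MT1F and MT2A stood at 0.82 ± 0.03, 0.73 ± 0.04 and 0.66 ± 0.05, while GCLM, a subunit of the enzyme that starts glutathione synthesis, stood at -0.93 ± 0.07. The list median was 0.43. This call was lost with median centring (adjusted p = 0.125), where 12 rose and 4 fell at a median of 0.26, and with spike-in scaling (adjusted p = 0.102), where 7 rose and 5 fell at a median of 0.04. Of 31 mesenchymal and extracellular matrix genes 20 rose and 7 fell (20 and 7 adjusted over the list alone; camera adjusted p = 0.0209, and adjusted p = 0.145 with an estimated correlation). The list median was 0.34 and turned to -0.01 with spike-in scaling. Camera still called the list upwards there (adjusted p = 0.0134), which again does not test the scaling. COL6A3, TIMP1, MMP2 and MMP14 stood at 1.27 ± 0.07, 1.18 ± 0.12, 1.06 ± 0.05 and 0.83 ± 0.05.

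Genes of the cell cycle and of chromatin duplication were lower in Bcl-xAS. Of 35 genes of G1/S and DNA replication 32 fell and 2 rose (32 and 2 adjusted over the list alone), with a median of -0.50 ± 0.02 (SD, n = 4) and camera adjusted p = 1.13e-08 (adjusted p = 0.123 with an estimated correlation). The replication helicase subunit gene MCM6, GINS2 and the maintenance methylation cofactor gene UHRF1 stood at -1.15 ± 0.05, -1.04 ± 0.02 and -0.91 ± 0.01, and the cyclin gene CCND1 rose to 0.94 ± 0.00. Of 36 genes of G2/M and mitosis 32 fell and 2 rose (32 and 2 adjusted over the list alone), with a median of -0.57 ± 0.02 and camera adjusted p = 4.14e-10 (adjusted p = 0.123 with an estimated correlation). The kinesin gene KIF20A, the cyclin genes CCNB2 and CCNB1 and the phosphatase gene CDKN3 stood at -1.39 ± 0.06, -0.96 ± 0.04, -0.85 ± 0.01 and -0.87 ± 0.02. Replication-dependent histone genes fell in 36 of 48 cases and rose in 9 (36 and 9 adjusted over the list alone), with a median of -0.67 ± 0.05 and camera adjusted p = 3.14e-07 (adjusted p = 0.292 with an estimated correlation). H4C5, H1-5, H4C8 and H3C2 stood at -1.65 ± 0.10, -1.51 ± 0.10, -1.40 ± 0.09 and -1.37 ± 0.10, and near-identical histone copies can share a probe. The medians of the G1/S, G2/M and histone lists moved to -0.72, -0.77 and -0.88 with median centring and to -0.85, -0.92 and -1.02 with spike-in scaling.

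Genes of RNA splicing, translation and respiration were lower on balance, by smaller amounts. Of 46 splicing regulators 33 fell and 5 rose (33 and 5 adjusted over the list alone), with a median of -0.21 ± 0.01 (SD, n = 4) and camera adjusted p = 1.12e-05 (adjusted p = 0.123 with an estimated correlation). The median moved to -0.42 with median centring, where 39 fell and 3 rose, and to -0.56 with spike-in scaling, where 41 fell and 1 rose. SRSF6, SRSF1 and KHDRBS1 stood at -1.11 ± 0.07, -1.04 ± 0.03 and -0.86 ± 0.03, and HNRNPC at -1.27 ± 0.05 over the 3 replicates that measured it. Ribosomal protein genes fell in 45 of 68 cases and rose in 14 (45 and 15 adjusted over the list alone), with a median of -0.24 ± 0.04 and camera adjusted p = 0.000545 (adjusted p = 0.263 with an estimated correlation). With median centring 65 fell and 0 rose, at a median of -0.54, and with spike-in scaling 59 fell and 0 rose, at -0.58. RPL7 and RPS3A stood at -0.88 ± 0.03 and -0.78 ± 0.02 over 3 replicates, RPS3 at -0.66 ± 0.04, and RPL22 at -0.72 ± 0.06 on its brighter probe and -1.86 on the other. Of 63 oxidative phosphorylation genes 36 fell and 8 rose (36 and 8 adjusted over the list alone; camera adjusted p = 0.000674, and adjusted p = 0.184 with an estimated correlation), including the ATP synthase genes ATP5F1D, ATP5PB and ATP5PO at -0.85 ± 0.10, -0.82 ± 0.04 and -0.46 ± 0.04 and the complex I gene NDUFB10 at -0.58 ± 0.08. The median of this list was -0.09; with median centring it was -0.35, where 61 fell and 0 rose, and with spike-in scaling -0.44, where 59 fell and 0 rose.

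**Figure D2:**
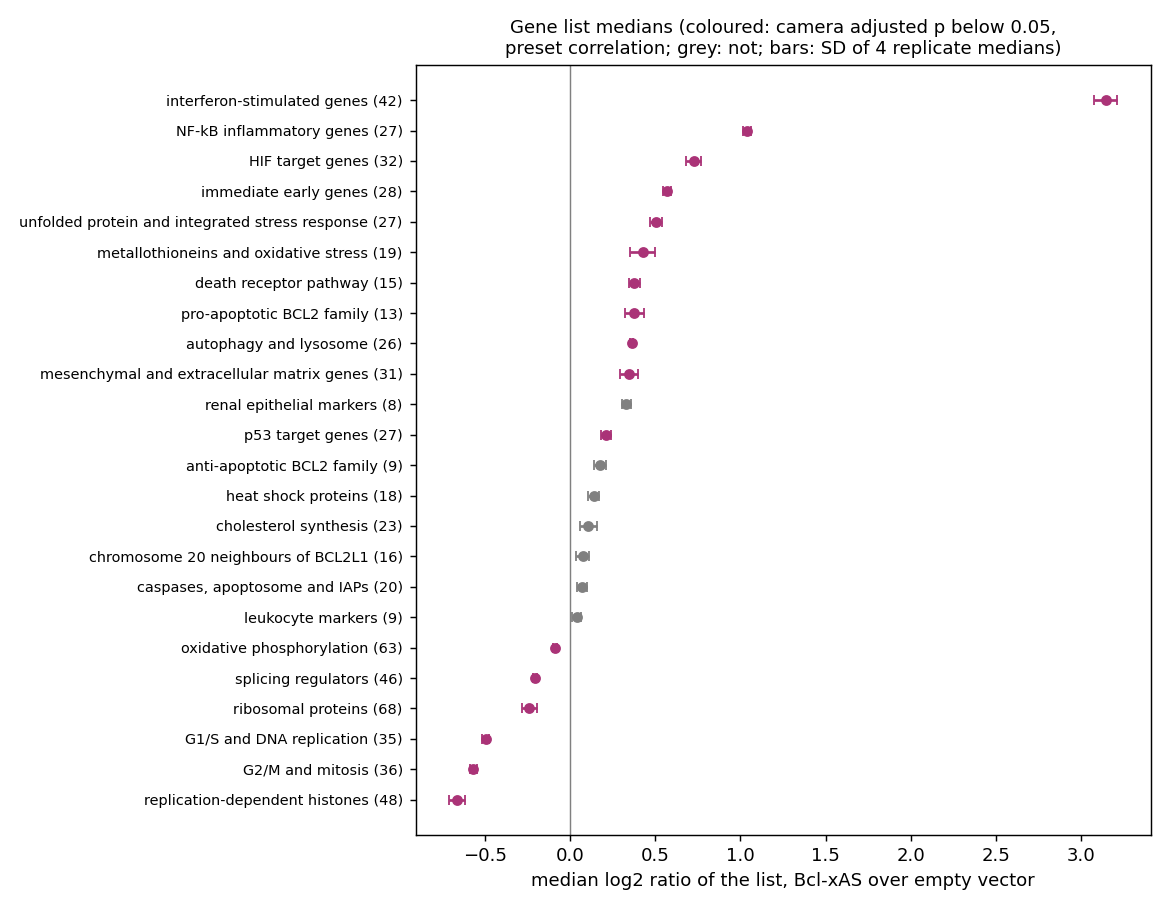
Median log2 ratio of Bcl-xAS over empty vector (x axis) for the 24 gene lists, with the number of tested genes in brackets; bars are the SD of the 4 replicate medians, coloured lists have a camera adjusted p below 0.05 with the preset correlation, and grey lists do not. Interferon-stimulated genes lie at 3.15, apart from the next list at 1.04, and replication-dependent histones lie lowest at -0.67.

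Bcl-xAS is named for the apoptosis regulator gene Bcl-x, so the apoptosis lists were compared as well. Among pro-apoptotic members of the BCL2 family, 8 of 13 rose and 2 fell (8 and 2 adjusted over the list alone; camera adjusted p = 0.0233, and adjusted p = 0.269 with an estimated correlation). With spike-in scaling 4 rose and 5 fell, and the list median moved from 0.38 to 0.02. Camera called the list upwards there (adjusted p = 0.00418), but the scaling shifts all genes of a replicate alike, so this does not test it. PMAIP1 and BBC3, which encode the BH3-only proteins NOXA and PUMA, stood at 2.46 ± 0.06 and 1.08 ± 0.03 (SD, n = 4) and BIK at 1.14 ± 0.04. BCL2L13 stood at 0.63 ± 0.04 on its brightest probe, but its other tested probes ranged from -0.62 to 0.29. The pro-apoptotic call was lost with median centring (adjusted p = 0.0554), with the deposited scanner log ratios (adjusted p = 0.0579), with the series value table (adjusted p = 0.0583) and on the Cy5 orientation alone (adjusted p = 0.0753). The list medians in these settings were, in that order, 0.22, 0.34, 0.34 and 0.33. In the anti-apoptotic list 7 of 9 rose and none fell (7 and 0 adjusted over the list alone). It was led by BCL2L2 at 0.61 ± 0.02, MCL1 at 0.33 ± 0.02 and BAG1, not itself of the BCL2 family, at 0.25 ± 0.00. With median centring 3 of the list rose and 1 fell, and with spike-in scaling 1 rose and 3 fell. MCL1 and BAG1 turned to -0.02 and -0.11 with spike-in scaling. The list as a whole did not pass the camera test (adjusted p = 0.102), and with spike-in scaling its median turned from 0.18 to -0.18.

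Death receptor genes rose in 11 of 15 cases and fell in 1 (11 and 1 adjusted over the list alone; camera adjusted p = 0.00432, and adjusted p = 0.127 with an estimated correlation). With spike-in scaling 5 rose and 5 fell, and the list median moved from 0.38 to 0.02. Camera called the list upwards there (adjusted p = 0.00735), which does not test the scaling, as all genes of a replicate shift alike. The ligand gene TNFSF10, which encodes TRAIL, and its receptor genes TNFRSF10A and TNFRSF10B stood at 1.27 ± 0.03, 1.20 ± 0.03 and 0.87 ± 0.06, and FAS at 1.17 ± 0.04 (SD, n = 4). Of 20 caspase, apoptosome and IAP genes 9 rose and 7 fell (10 and 7 adjusted over the list alone; camera adjusted p = 0.671). The list median was 0.07. It turned to -0.12 with median centring, where 5 rose and 10 fell, and to -0.28 with spike-in scaling, where 4 rose and 13 fell. With the scanner log ratios and with the series value table it was -0.02, and 6 rose and 7 fell in each. CASP1, the inflammatory caspase, stood at 2.74 ± 0.42, with empty vector RNA well above background on 6 of 8 arrays. CASP4, BIRC3 and BIRC5 stood at 1.19 ± 0.04, 1.39 ± 0.07 and -0.54 ± 0.03. Of 27 p53 target genes 17 rose and 7 fell (17 and 7 adjusted over the list alone; camera adjusted p = 0.0388, and adjusted p = 0.263 with an estimated correlation). GDF15 and GADD45A stood at 2.77 ± 0.21 and 1.58 ± 0.03. The p53 call was lost without replicate 1 (adjusted p = 0.0539) and among probes well above background on all arrays (adjusted p = 0.0541). The list medians there were 0.19 and 0.21. With spike-in scaling the list median turned from 0.21 to -0.14. Camera called the list upwards under that scaling (adjusted p = 0.00017), which likewise does not test it.

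The sense gene BCL2L1 was measured by 1 probe, which was well above background on all 8 arrays in both RNAs. Its log2 ratio was 0.21 ± 0.05 (SD, n = 4), a 1.15-fold rise that was positive in 4 of 4 replicates (limma adjusted p = 0.000102). With median centring the log2 ratio was 0.08 and did not pass (adjusted p = 0.140), and with spike-in scaling it was -0.15 and did not pass (adjusted p = 0.167). No probe was assigned to Bcl-xAS itself, so the level of the transfected RNA is not reported here. Among 16 genes that neighbour BCL2L1 on chromosome 20, 7 rose and 4 fell (7 and 4 adjusted over the list alone; camera adjusted p = 0.626). The list median was 0.07 and turned to -0.28 with spike-in scaling, where 1 rose and 11 fell. TPX2 and MYLK2 stood at -0.54 ± 0.04 and -0.33 ± 0.05. HM13 stood at 0.80 ± 0.06 on its brightest probe, with other tested probes from -0.61 to 0.72. KIF3B stood at 0.27 ± 0.04 and turned to -0.08 with spike-in scaling.

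The remaining lists passed no camera test with the scaling used here. With spike-in scaling the medians of heat shock, cholesterol and renal epithelial genes turned from 0.14, 0.11 and 0.33 to -0.22, -0.25 and -0.02. With median centring the heat shock median was -0.075, where 6 rose and 9 fell. The cholesterol median was -0.038 with median centring, where 8 rose and 9 fell. Of 18 heat shock protein genes 10 rose and 4 fell (10 and 5 adjusted over the list alone; adjusted p = 0.277), with HSPA1B, HSPA1A and DNAJA1 at 1.06 ± 0.05, 0.71 ± 0.02 and 0.58 ± 0.00 and the mitochondrial co-chaperonin gene HSPE1 at -0.41 ± 0.03. Of 23 cholesterol synthesis genes 12 rose and 6 fell (12 and 7 adjusted over the list alone; adjusted p = 0.337), with STARD4, MSMO1 and CYP51A1 at 0.99 ± 0.03, 0.56 ± 0.05 and 0.54 ± 0.04. CYP51A1, like EPCAM among the renal epithelial markers, no longer passed with spike-in scaling, at 0.19 and 0.15. Of 8 renal epithelial markers 6 rose and 1 fell (6 and 2 adjusted over the list alone; adjusted p = 0.129), among them the cadherin gene CDH16 at 2.02 ± 0.03, KRT18 at 0.71 ± 0.06 and EPCAM at 0.51 ± 0.05. PAX2 stood at -0.49 ± 0.02 on its brightest probe and 0.02 on the other. Of 9 leukocyte markers 4 rose and 2 fell (4 and 2 adjusted over the list alone; adjusted p = 0.320), with CD68 at 2.40 ± 0.09, CD3E at 1.16 ± 0.12, CD14 at 0.58 ± 0.02 and CD4 at 0.23 ± 0.03. CD4 turned to -0.02 with median centring and to -0.12 with spike-in scaling. With spike-in scaling the median of the leukocyte list was -0.32 although its camera test pointed upwards (adjusted p = 0.0363). The scaling shifts all genes of a replicate alike, so this does not show the list moving against other genes.

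Long intergenic non-coding RNAs fell more often than they rose. Of 6410 tested lincRNA probes, 147 were at least 1.5-fold higher and 384 at least 1.5-fold lower. The counts depended on the processing. Of the probes at least 1.5-fold changed, 126 of 623 were higher with median centring, 289 of 1226 with the scanner log ratios and 66 of 1166 with spike-in scaling. The rising probes of smallest p lay in transcripts at chromosome 13 from 106751024 to 106760449, chromosome 12 from 5351264 to 5359564 and chromosome 1 from 89874262 to 89947412 (hg19, from the probe names). Their log2 ratios were 2.47 ± 0.08, 1.94 ± 0.08 and 1.92 ± 0.08 (SD, n = 4). The probe on chromosome 1 was not well above background in empty vector RNA on any array, so its rise is at least 3.41-fold, a bound set by the lowest signals well above background. The falling probes of smallest p lay at chromosome 2 from 38358246 to 38408993, chromosome 11 from 65265824 to 65275174 and chromosome 8 from 129000922 to 129004320. Their log2 ratios were -1.88 ± 0.06, -1.88 ± 0.07 and -1.61 ± 0.02.

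The dye swap and the replicates were compared to see how far a single array can be trusted. Log2 ratios averaged over both dyes correlated across probes with Pearson r between 0.962 and 0.978 for the 6 pairs of replicate numbers. Single arrays of one orientation correlated with r between 0.911 and 0.960, and the 2 orientations of one replicate number with r between 0.790 and 0.862 (median 0.837). Opposite orientations of different replicate numbers gave r between 0.791 and 0.864 (median 0.843), so arrays of one number agreed no better than arrays of different numbers. Probes are not independent replicates, so these r carry no p. A dye effect per probe was found for 9384 of 33558 tested probes (limma, adjusted p 0.05), with a median size of 0.07 and a 95th percentile of 0.22 on the log2 scale, and only 17 probes reached 1.5-fold. Without replicate 3 this count was 5077, and without each of the others in turn at most 7251.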

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

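The tests of the interferon-stimulated genes, of the spike-in RNAs and of the low signal of lincRNA probes were chosen only after the result was seen. For 12 of 138 sets of 4 replicate values 1 replicate stood apart from the other replicates (8.70%), where chance sets apart about 5%. Replicate 1 stood apart for CMPK2 at a log2 ratio of 4.93 (mean of the other replicates 4.78), NT5DC2 at -1.84 (-1.67), PMAIP1 at 2.56 (2.43) and IL6 at 1.65 (1.62). Replicate 2 stood apart for MX1 at 4.38 (4.25) and MT2A at 0.74 (0.64), and replicate 3 for MYLK2 at -0.26 (-0.35). Replicate 4 stood apart for AGPS at -1.83 (-1.69), KLF4 at 2.78 (2.93), H4C8 at -1.54 (-1.35), HK2 at 1.32 (1.28) and the mean of the cholesterol synthesis list at 0.20 (0.16). In each case the replicate had the direction of the others.

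Interferon-stimulated genes were higher in Bcl-xAS, with a list median of 3.15. Gene-specific dye bias is argued against by a median of 3.07 in the orientation where it was smaller. The normalization used here is argued against by medians of 3.02 with median centring and 3.46 with the scanner log ratios. Spike-in scaling gave 2.79, but it lowers every gene by 0.35 on average, so it could not have removed a rise of this size. A difference between the 2 plasmid preparations other than the encoded RNA cannot be told apart from an effect of Bcl-xAS, because the design has 1 kind of control plasmid, the empty vector. Either may underlie the rise.

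The 10 E1A spike-in RNAs, which are added at labelling and entered the results only as an alternative scaling, were higher in the Bcl-xAS channel by 0.35 ± 0.18 (SD, n = 4) on the log2 scale, or 1.28-fold, at 0.51, 0.50, 0.26 and 0.14 in replicates 1 to 4. The loess fit is argued against as the whole cause by a mean of 0.20 with median centring, at which the shift was smaller. Uneven addition of spike-in mix between labellings stays open: all 4 replicates had one sign, but the exact two-sided sign-flip p = 0.125 is the smallest that 4 replicates allow. A lower messenger RNA content of the total RNA in Bcl-xAS may give the same shift, and it was not tested.

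Of lincRNA probes at least 1.5-fold changed, 147 of 531 (27.7%) were higher, against 62.3% of messenger RNA probes matched on intensity. Low signal of lincRNA probes is argued against by that gap of 34.6 points, and several probes of a few lincRNAs counted repeatedly by a gap of 31.9 points with 1 probe per lincRNA. The normalization used here left a gap of at least 26.2 points under median centring, no background correction and the scanner log ratios. With spike-in scaling, added after seeing the data, the gap was 8.0 points (5.66% against 13.7%), because few probes of either kind were higher there, so a part played by the scaling stays open. No biological explanation was tested.

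Other arrangements of the samples were counted for genes and lists. With the sign of the 4 replicate ratios turned in other ways, 8 patterns are possible, which is too few for a share under 0.05; 1 pattern, the real one, reached 12020 genes, and the highest other gave 0. For lists, 1 of the 8 patterns reached 17, and the highest other gave 15. With the RNAs unpaired, 1 of 35 splits, the real one, reached 8144 genes, and the highest other, replicates 1 and 4 against 2 and 3, gave 465. Only 8 of these splits part both RNAs of every replicate number, which share arrays; these are too few for a share under 0.05, and the highest other among them gave 2 genes. The remaining splits put both RNAs of at least 1 replicate number on one side. For lists, 3 of the 35 splits gave 17 or more and the highest other gave 18, so chance is not excluded by this count. Both others that reached 17 join 3 RNAs of one kind with 1 of the other and so carry part of the real difference, with medians of the interferon-stimulated list of 1.61 and -1.53. The splits with 2 RNAs of each kind on a side gave at most 2 lists.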

How the results depend on the processing

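Spike-in scaling, each slide column alone, replicates 2 and 4 counted as 1 and adjustment over genes alone were chosen after seeing the data. Of 3074 values of the 134 named genes and probes under alternatives, 3061 kept direction and side of the threshold, 7 lost significance and 6 reversed: with spike-in scaling MCL1 (-0.025), BAG1 (-0.11), BCL2L1 (-0.15), KIF3B (-0.082) and CD4 (-0.12), and with median centring CD4 (-0.024). Most of the named genes and probes were chosen for a large ratio or small p in these same data, and Aquantile leaves ratios unchanged. The share that kept its place therefore says little about other genes. BCL2L1 lay between -0.15 and 0.29 over the alternatives and at 0.085 with median centring. No gene at least 1.5-fold changed was called at least 1.5-fold in the opposite direction under any alternative of the gene counts. Genes at least 1.5-fold lower numbered 1741 with Feature Extraction log ratios, 1745 with the series values and 1627 with median centring, against 936. With spike-in scaling 1723 genes were higher and 10887 lower, and 728 higher and 3253 lower by at least 1.5-fold, because that scaling moves all ratios down. Requiring 1.5-fold as well as adjusted p left 2545 genes. The 4 fits that leave out a replicate gave between 11219 and 11650 genes, and counting replicates 2 and 4 as 1 gave 11788. Without the replicate block, with the RNAs unpaired, 8144 genes passed. The preset-correlation camera adjusted p of the pro-apoptotic list ranged from 0.00314 to 0.0753. It was 0.0579 for Feature Extraction log ratios, 0.0554 for median centring, 0.0753 for the Cy5 orientation alone and 0.0583 for the series values. That of p53 targets ranged from 0.000173 to 0.0541, with 0.0541 for probes well above background on all arrays and between 0.0259 and 0.0539 without each replicate in turn, losing the call without replicate 1. That of metallothioneins and oxidative stress ranged from 0.00197 to 0.125, with 0.125 for median centring and 0.102 for spike-in scaling. The caspase list reversed with median centring (0.949), the chromosome 20 neighbours with spike-in scaling (0.948) and slide column 1 alone (0.987), all short of the threshold. Leukocyte markers passed with spike-in scaling (0.0363). That scaling shifts all genes of a replicate alike, so camera results under it do not test the scaling. With an estimated correlation none of the 17 called lists passed: adjusted p was 0.123 for interferon-stimulated, NF-kB, immediate early, G1/S, G2/M, HIF, splicing and autophagy genes, 0.127 for death receptors, 0.137 for metallothioneins, 0.145 for mesenchymal genes, 0.184 for the stress response and oxidative phosphorylation, 0.263 for p53 targets and ribosomal proteins, 0.269 for pro-apoptotic genes and 0.292 for histones. With fry, which does not compare a list with other genes, the 7 other lists passed too: anti-apoptotic 3.49e-05, caspases 0.00123, heat shock 0.0013, cholesterol 0.000375, chromosome 20 neighbours 0.0415, leukocyte 4.47e-05 and renal 1.06e-05. The dye effect per probe passed for between 5077 and 7251 probes without each replicate in turn, fewest without replicate 3. Agreement of the replicates was 0.979 among probes well above background on all arrays and 0.917 with Feature Extraction log ratios. Apart from what the settings' construction shows, the cause was not tested. Signal over background limits the ratios of dim probes, which the offset shrinks.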

Other observations

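All gene groups in this part were chosen after the values were seen, and the tests were chosen only after the result was seen. Genes of MHC class I antigen presentation were higher in Bcl-xAS: 17 of 18 tested rose and none fell, with a median log2 ratio of 1.21 (camera adjusted p = 9.84e-07, and 0.119 with an estimated correlation). The peptide transporter gene TAP1 stood at 2.96 ± 0.03, B2M, the light chain of MHC class I, at 2.45 ± 0.10, the immunoproteasome gene PSMB9 at 2.25 ± 0.05 and HLA-E at 1.94 ± 0.07 (SD, n = 4). Of 14 complement genes 11 rose and 2 fell, with a median of 1.06 (adjusted p = 0.000757, and 0.119 with an estimated correlation). C1R, CFB and C3 stood at 3.33 ± 0.08, 2.74 ± 0.08 and 2.15 ± 0.10, and C5 at -0.89 ± 0.07.

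Of 16 genes for sensors of foreign nucleic acid, 2 of which are also in the interferon-stimulated list, 13 rose and 2 fell, with a median of 1.5 (adjusted p = 7.32e-05, and 0.181 with an estimated correlation). IFIH1 and RIGI, which sense double-stranded RNA, stood at 3.71 ± 0.04 and 3.37 ± 0.08, and DDX60 at 2.35 ± 0.07. Of 5 tested interferon genes, 3 of which are also in the interferon-stimulated list, 3 rose and 1 fell. The group did not pass (camera adjusted p = 0.284, and 0.398 with an estimated correlation). IFNB1 stood at 0.74 ± 0.05 and IFNL1 at 0.48 ± 0.05, which fell to 0.13 and no longer passed with spike-in scaling. The probes of IFNB1 and IFNL1 were dim, at mean log2 intensities of 7.10 and 7.23, where the offset shrinks ratios. Of 14 small nucleolar RNA host genes 5 rose and 8 fell, with a median of -0.30, and the group did not pass (adjusted p = 0.211, and 0.303 with an estimated correlation). SNHG3 and SNHG10 stood at -1.41 ± 0.02 and -0.93 ± 0.01, and ZFAS1 at 1.07 ± 0.06.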
